A study of Arabidopsis thaliana with 36 samples.

How the data were processed

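The material was RNA from cotyledons and hypocotyls dissected from Arabidopsis thaliana Col-0 seedlings. Per the labels, the seedlings stayed in high R/FR or were moved to low R/FR, and both organs were collected at 0 min (high R/FR only) and after 15, 45, 90 and 180 min. Each of the 18 groups had 2 libraries, 36 in all. The labels describe 1 plate of seedlings per sample and record no separate cultures or days, so p-values here measure the spread between samples.

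Per the submitters' processing notes, the software was cutadapt 1.2.1, TopHat2 2.0.9, Bowtie, HTSeq 0.5.4p3, edgeR 3.4.0 and limma 3.18.2 with the TAIR10 annotation; the notes do not say which step used which setting. The deposited count files hold raw read counts per gene for 33602 genes, followed by 5 summary lines of the HTSeq type. The authors' deposited tables of each organ hold log2 fold changes of low over high R/FR at each of the 4 times. They also hold the authors' p-values and adjusted p-values, and the deposited adjusted values equal a Benjamini-Hochberg adjustment over the 4 times of the organ together. Those tables list 20957 genes, of which 20120 were also tested here, and they were used only for the comparison at the end of the report, for gene positions and for gene descriptions.

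Everything else was computed here from the deposited counts, in R 4.3.3. The 5 summary lines were left out of library sizes and tests. Percentages here are of the sum of gene counts, reads without a feature and ambiguous reads. Reads without a feature made up 0.811 to 1.5% in cotyledon and 1.05 to 2.89% in hypocotyl, and ambiguous reads 0.382 to 0.623% and 0.66 to 0.807%. Non-unique alignments numbered 9.96 to 20.21 per 100 gene counts in cotyledon and 7.24 to 39 in hypocotyl. Gene identifiers were matched to a RefSeq gene table, which held 32835 of them, and exonic length and GC content were computed from the RefSeq annotation and genome for 20003 of the tested genes. Library sizes were scaled by the trimmed mean of M values (TMM), with factors of 0.767 to 0.854 in cotyledon and 1.185 to 1.29 in hypocotyl. Genes with too few counts were removed with the edgeR filter at its minimum count of 10 and minimum total of 15, which left 20126 genes.

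Tests used edgeR 4.0.16, with a robust quasi-likelihood fit of 1 mean per group over all 36 libraries and 18 residual degrees of freedom. The median prior degrees of freedom were 10.5 and the common biological coefficient of variation 0.0763. Contrasts compared low with high R/FR at each time in each organ, the response of the hypocotyl with that of the cotyledon at each time, and 180 with 0 min in high R/FR in each organ. The organs were compared in the 20 high R/FR libraries with time and organ as terms, 14 residual degrees of freedom and 19825 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Counts were scaled to CPM with the TMM library sizes, and log values a prior count of 2. Where a group had no counts, a bound was taken from a floor of 3 counts over the group. With 1 to 3 counts a 95% counting interval is given, and both cover counting error alone.

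Gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with adjustment over the lists within each comparison; the estimated correlation was the alternative. The lists held shade markers, auxin synthesis, auxin transport, Aux/IAA, SAUR and GH3 genes, and genes of brassinosteroid metabolism, gibberellin metabolism and receptors, and ethylene synthesis. Others held expansins, XTH genes, primary wall cellulose synthases, and genes of photosynthesis, the circadian clock, photoreceptors and light signalling, flavonoids, the cell cycle and carbon starvation. The remaining lists held genes of jasmonate, touch and wounding, salicylate defence and heat shock, and markers of root, shoot apex, stomatal lineage and vascular tissue. Named genes were drawn by a fixed rule. It takes the panel of 8 in every light comparison, and up to 3 rising and 3 falling genes with the largest change among called genes with an average log2 CPM of at least 1 and no overlap between the libraries of the groups. Differences between the organs' responses used the same rule without the overlap condition, and the organ comparison took 5 each way. From each list described, it takes up to 4 called members with the smallest p, or up to 2 where none was called. Of the genes drawn by this rule, 2 are not reported here. Families of genes in the closing section were taken from the authors' deposited descriptions by matching their words with case; ignoring case, which was tried for low R/FR at 180 min in hypocotyl, changed the call of 1 of the families, vesicle coat proteins (estimated correlation, camera adjusted p of 0.0214 with 22 genes against 0.145 with 9).

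Replicates were checked for copies: the chi-square per degree of freedom between the 2 libraries of a group ran from 3.645 to 20.16, where a copied library would give values far under 1. The spread between them had a log2 size of 0.168 to 0.295. The pipeline was tested on simulated data with the spread of these libraries, in which a small set of genes was changed by known folds. In each changed comparison 67, 67 and 66 genes were changed 1.5-, 2- and 4-fold, up or down at random. Where the real comparisons called far larger shares of the genes, these rates and false calls need not hold. Of genes changed 1.5-, 2- and 4-fold it called 55.2, 76.1 and 86.4% in the cotyledon comparison at 180 min, with 3 false calls. In the hypocotyl comparison at 90 min it called 64.2, 77.6 and 95.5%, with 7 false calls, and in the difference between organs at 90 min 26.9, 70.1 and 89.4%, with 3. The organ comparison reached 71.6, 94 and 100%, with 7 false calls, and an unchanged comparison at 15 min in cotyledon gave 0.

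The alternatives tried were relative log expression (RLE) size factors, no low-count filter, the DESeq2 1.42.0 Wald test, limma-voom, and a fit of each organ's own 18 libraries. Replicate numbers were used as blocks across lights and across organs, each library was left out in turn, and a minimum 2-fold test was run between the organs. A fit without the library with the most non-unique alignments and a fit without the 4 libraries numbered 3 were chosen after seeing the data. Near-identical copies, such as members of the SAUR19 to SAUR24 and SAUR61 to SAUR68 clusters and the LHCB1 genes, share sequence, so the counts of single members are uncertain. Transcript isoforms, spliced reads and sequence variants could not be examined, because reads and alignments were not analysed here.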

Results

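Gene counts were available for 36 RNA sequencing libraries of cotyledons and hypocotyls dissected from Arabidopsis thaliana seedlings of the Col-0 accession. Per the labels, the seedlings were either kept in white light with a high red to far-red ratio (high R/FR) or moved to a low ratio that simulates shade from neighbouring plants (low R/FR). Both organs were collected after 15, 45, 90 and 180 min in each light and at 0 min in high R/FR, which makes 18 groups of 2 libraries. Gene counts per library ran from 24897594 to 45115165 in cotyledon and from 23560273 to 34231167 in hypocotyl. Of 33602 genes in the count tables, 20126 had enough counts to be tested. The 10 most abundant genes took 12.2 to 16.0% of the gene counts in cotyledon and 5.0 to 8.0% in hypocotyl. Changes are log2 ratios of low over high R/FR with their SE, from 2 libraries per group, and adjusted p is the Benjamini-Hochberg value of the edgeR quasi-likelihood test.

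The 8 shade-response genes followed through every light comparison were fixed before the data were examined, and their positions (TAIR10) were taken from the authors' deposited tables. PIL1 (AT2G46970; chromosome 2, 19295490 to 19297826) and HFR1 (AT1G02340; chromosome 1, 465718 to 467844) encode basic helix-loop-helix transcription factors, and ATHB2 (AT4G16780; chromosome 4, 9449114 to 9450743) a homeodomain-leucine zipper factor. XTH15 (AT4G14130; chromosome 4, 8137051 to 8138281) encodes a xyloglucan endotransglucosylase/hydrolase, a cell wall enzyme. YUC8 (AT4G28720; chromosome 4, 14192583 to 14194256) and YUC9 (AT1G04180; chromosome 1, 1104623 to 1105988) encode flavin monooxygenases of auxin synthesis. IAA19 (AT3G15540; chromosome 3, 5264024 to 5265678) and IAA29 (AT4G32280; chromosome 4, 15583387 to 15584769) encode Aux/IAA repressors of auxin signalling.

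**Figure D1:**
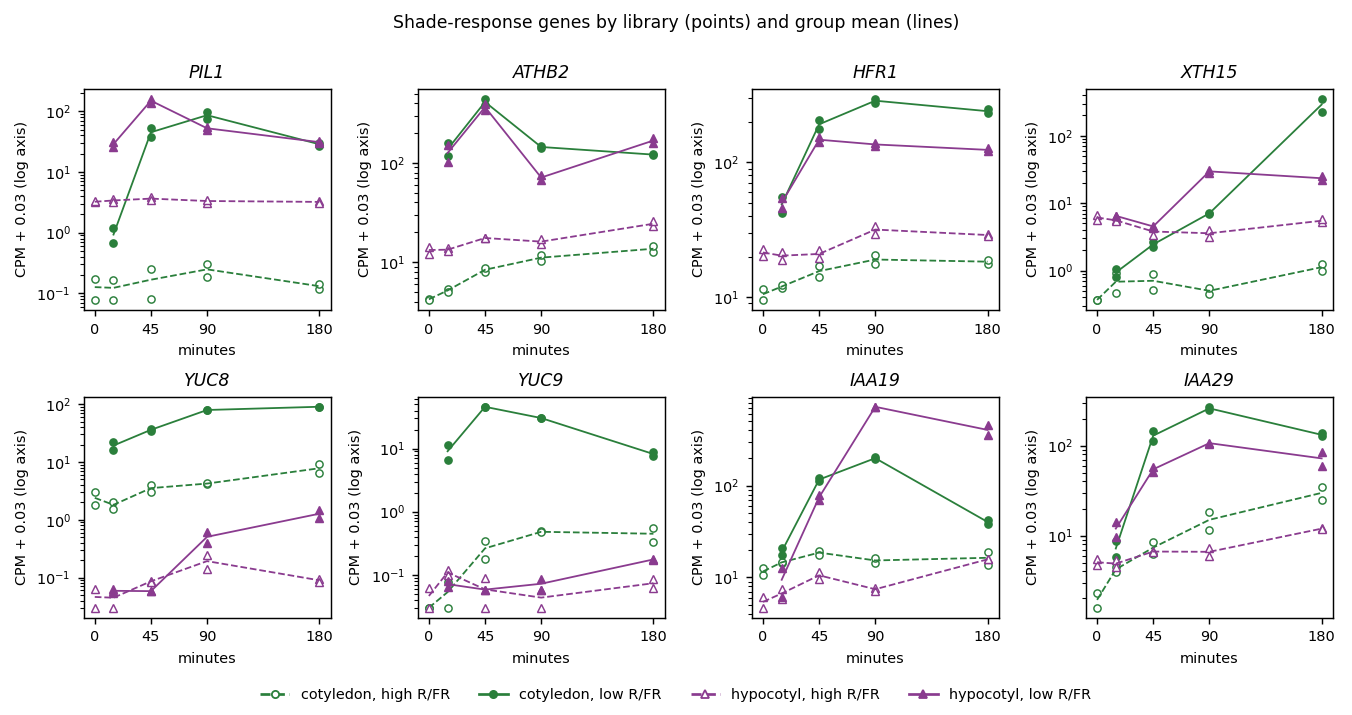
Expression (CPM, plus 0.03, log axis) of the 8 shade-response genes against minutes in cotyledon (circles) and hypocotyl (triangles), in high R/FR (open, dashed) and low R/FR (filled, solid), with points for libraries and lines for means of 2 libraries. After 45 min of low R/FR the mean of ATHB2 was 411 CPM in cotyledon and 365 CPM in hypocotyl, against 8.36 and 17.5 CPM in high R/FR.

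The comparison of low with high R/FR in cotyledon at the same time asks which genes respond to simulated shade in this organ, and how soon. Within 15 min, cotyledons held more transcript of shade markers and of auxin synthesis genes. ATHB2 rose from 5.16 ± 0.207 to 137 ± 27.6 CPM (SD, n = 2), a log2 change of 4.73 ± 0.18, and its relatives ATHB4 and HAT1 rose by 4.95 ± 0.32 and 1.57 ± 0.15. HFR1 rose by 2.03 ± 0.13. YUC8 rose by 3.43 ± 0.21, YUC5 by 2.65 ± 0.27 and YUC2 by 1.1 ± 0.14. YUC9 had 1 count over the high R/FR pair and 411 over the low R/FR pair, a CPM ratio of 389 with a 95% counting interval of 69.4 to 15400. In total 44 genes were higher and 0 lower, 26 by at least 2-fold. For 652, fewer than chance would give, unadjusted p was below 0.05. The number of lower genes was also 0 with DESeq2, limma-voom and RLE scaling, which called 65, 40 and 46 genes higher. Of 17 shade markers 7 rose (11 adjusted over the list alone, camera adjusted p = 4.52e-128), as did 4 of 8 auxin biosynthesis genes (4 adjusted over the list alone, camera adjusted p = 2.17e-60). Of 27 SAUR genes, small auxin-induced genes, 4 rose (10 adjusted over the list alone, camera adjusted p = 5.85e-27), with SAUR19 at 1.76 ± 0.28 and SAUR20 at 1.05 ± 0.18. PIL1 averaged 3.22 ± 0.71 and did not pass in the reported test (adjusted p = 0.0557), but did with RLE scaling, DESeq2 or replicate numbers as blocks. XTH15, IAA19 and IAA29 stood at 0.47, 0.39 and 0.78 (adjusted p = 1). GH3 genes, whose enzymes conjugate auxin to amino acids, had 0 of 6 members called (0 adjusted over the list alone) beside a camera adjusted p of 0.00412, and adjusted p = 0.108 with an estimated correlation. The Aux/IAA list had 1 of 27 members called (2 adjusted over the list alone), a median of 0.084 and a mean of -0.093, with camera upward at adjusted p = 0.025 and adjusted p = 0.478 with an estimated correlation. Without high R/FR library 1, high R/FR library 2 or low R/FR library 1 the count of higher genes was 25, 26 and 26, and SAUR19 lost its call without high R/FR library 2 (adjusted p = 0.113).

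At 45 min the response in cotyledon covered auxin synthesis, auxin response and hormone conjugation genes. PIL1 rose by 8.28 ± 0.31, ATHB2 by 5.62 ± 0.18, HFR1 by 3.62 ± 0.13 and CKX5, a cytokinin oxidase, by 6.47 ± 0.32. YUC9 rose by 7.58 ± 0.29, YUC8 by 3.35 ± 0.18 and YUC2 by 1.87 ± 0.14. The auxin response genes IAA29, IAA5, IAA19 and IAA2 rose by 4.14 ± 0.26, 4.01 ± 0.26, 2.64 ± 0.21 and 2.09 ± 0.14, and the GH3 genes GH3.3 and GH3.6 by 4.81 ± 0.23 and 3.1 ± 0.29. ST2A, a sulfotransferase that acts on hydroxyjasmonate, was higher by a CPM ratio of 98.1 (95% counting interval 33.3 to 478). The largest falls were in AT5G54145 (-2.74 ± 0.24), AT5G45850 (-2.61 ± 0.39) and WAVH2, a member of the WAVY GROWTH family (-2.54 ± 0.14). Of 20126 genes 465 were higher and 263 lower, 269 of them by at least 2-fold. Shade markers rose in 16 of 17 cases (17 adjusted over the list alone, camera adjusted p = 1.19e-158) and SAUR genes in 21 of 27 (22 adjusted over the list alone; 2.74e-111), among them SAUR22 at 4.22 ± 0.23 and SAUR29 at 2.21 ± 0.14. Aux/IAA genes rose in 14 of 27 cases and fell in 1 (15 and 1 adjusted over the list alone; 5.64e-31). Brassinosteroid metabolism genes rose in 5 of 13 cases and fell in 1 (7 and 1 adjusted over the list alone; 4.21e-12), led by DWF4 at 1.68 ± 0.10 and BR6OX2 at 1.16 ± 0.15, both enzymes of brassinosteroid synthesis. Of 12 ethylene biosynthesis genes 4 rose (4 adjusted over the list alone; 3.13e-07), with the ACC synthases ACS8 and ACS4 at 5.56 ± 0.36 and 2.87 ± 0.25. Auxin transport genes rose in 4 of 15 cases (5, and 1 fall, adjusted over the list alone; 2.81e-05), with the influx carrier AUX1 at 1.23 ± 0.07 and the efflux protein PIN3 at 0.87 ± 0.13. PHYB, the photoreceptor phytochrome B, rose by 1.60 ± 0.08 while the phytochrome-interacting factors PIF1 and PIF7 fell by 0.64 ± 0.11 and 0.41 ± 0.08; in its list 1 of 19 rose and 3 fell (2 and 8 adjusted over the list alone; 0.455). KAT1, a potassium channel of guard cells, rose by 2.90 ± 0.13, the only call in a stomatal lineage list of 8 whose camera test passed (1 adjusted over the list alone; 1.93e-06). Expansins rose in 2 of 14 cases (3, and 1 fall, adjusted over the list alone) at a camera adjusted p of 0.0152, with adjusted p = 0.319 with an estimated correlation. XTH15 rose by 1.82 ± 0.37 (adjusted p = 0.00254) and lost its call without high R/FR library 2 (adjusted p = 0.0774). The count of changed genes was 433 without high R/FR library 1, 471 without low R/FR library 2 and 2132 without low R/FR library 1.

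At 90 min all 6 GH3 genes tested from the list were higher in cotyledon, and falls outnumbered rises among all called genes. PIL1 and HFR1 stood at 8.66 ± 0.25 and 3.91 ± 0.13, CKX5 at 7.54 ± 0.27, YUC8 at 4.23 ± 0.16 and YUC9 at 6.07 ± 0.25, while ATHB2 stood at 3.70 ± 0.16. XTH15 rose by 3.87 ± 0.29, IAA19 by 3.70 ± 0.21, IAA29 by 4.1 ± 0.24 and ST2A by 8.84 ± 0.31. TAA1, the tryptophan aminotransferase that acts before the YUC enzymes, fell by 2.43 ± 0.17. In total 888 genes were higher and 1279 lower, 658 by at least 2-fold. GH3 genes rose in 6 of 6 cases (6 adjusted over the list alone, camera adjusted p = 5.63e-27), with GH3.3 at 6.25 ± 0.20 and GH3.1, at 0 counts in the high R/FR pair, at least 28.2-fold higher. Shade markers rose in 14 of 17 cases (14, and 1 fall, adjusted over the list alone; 1.98e-82), Aux/IAA genes in 19 with 2 falls of 27 (20 and 2 adjusted over the list alone; 8.14e-30). Auxin biosynthesis genes rose in 5 and fell in 2 of 8 (5 and 2 adjusted over the list alone; 1.56e-12). IAA5, IAA30 and IAA34 rose by 4.52 ± 0.23, 5.19 ± 0.37 and 4.31 ± 0.31. SAUR genes now moved both ways, with 18 rises and 2 falls of 27 (20 and 2 adjusted over the list alone; 2.70e-21), SAUR10 at 4.2 ± 0.27 and SAUR14 at -1.23 ± 0.12. Auxin transport genes rose in 10 of 15 cases and fell in 3 (10 and 3 adjusted over the list alone; 1.87e-06), with ABCB4 at 2.33 ± 0.17 and LAX3 at -1.26 ± 0.16. In the brassinosteroid list 2 of 13 rose and 3 fell (5 and 3 adjusted over the list alone; 0.304). The synthesis enzymes ROT3, BR6OX1 and DWF4 changed by -3.09 ± 0.21, -2.63 ± 0.29 and -1.2 ± 0.10, with the inactivating enzyme BAS1 at 1.70 ± 0.26. XTH genes fell in 10 of 22 cases and rose in 3 (10 and 3 adjusted over the list alone; 0.347), with a median of -0.276 and a mean of 0.011. PHYA rose by 1.67 ± 0.08 and PHYB by 1.87 ± 0.08, while PIF7 and PIF4 fell by 1.16 ± 0.08 and 0.90 ± 0.09. Flavonoid genes rose in 5 of 14 cases and fell in 1 (5 and 1 adjusted over the list alone; 0.00816, and adjusted p = 0.27 with an estimated correlation), with the regulator MYB111 at 2.86 ± 0.27. The gibberellin list had 5 rises and 1 fall of 18 (5 and 2 adjusted over the list alone; 0.0481, and adjusted p = 0.0628 with an estimated correlation). The catabolic enzyme GA2OX6 rose by 4.38 ± 0.34 and the synthesis enzyme GA20OX3 by a ratio of 109 (95% counting interval 19 to 4370).

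At 180 min cotyledons held far more XTH15 transcript, transcript of the cytochrome P450 CYP96A5, and less transcript of several expansins and clock genes. XTH15 rose by 8.06 ± 0.21, ST2A by 10.00 ± 0.29 and PIL1 by 8.07 ± 0.33. CYP96A5 had 0 counts in the high R/FR pair and was at least 666-fold higher. HFR1 (3.71 ± 0.13), ATHB2 (3.15 ± 0.16), YUC8 (3.53 ± 0.16) and YUC9 (4.3 ± 0.29) stayed high, while IAA19 and IAA29 stood at 1.29 ± 0.21 and 2.14 ± 0.22. The expansins EXPA5 and EXPA1, wall-loosening proteins, fell by 3.09 ± 0.15 and 1.67 ± 0.19. In total 1615 genes were higher and 2314 lower, 901 by at least 2-fold, but with the organ's own 18 libraries 1988 were higher and 1805 lower. Shade markers rose in 9 of 17 cases and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 2.55e-36), the fall being PRE1, a helix-loop-helix protein, at -1.79 ± 0.20. SAUR genes were split, with 7 rises and 6 falls of 27 (7 and 7 adjusted over the list alone, camera adjusted p = 0.412), SAUR22 at 2.54 ± 0.21 and SAUR14 at -1.57 ± 0.13. Aux/IAA genes rose in 13 of 27 cases and fell in 3 (13 and 4 adjusted over the list alone, camera adjusted p = 1.54e-06, and adjusted p = 0.0685 with an estimated correlation), with IAA34 at 4.50 ± 0.30 and IAA7 at 1.21 ± 0.07. GH3 genes rose in 3 of 6 cases (3 adjusted over the list alone, camera adjusted p = 1.38e-06), with GH3.3 at 5.54 ± 0.18. Auxin biosynthesis genes had 3 rises and 2 falls of 8 (3 and 2 adjusted over the list alone), a median of -0.11, a mean of 0.621 and an upward camera test at 0.00512, with adjusted p = 0.0601 with an estimated correlation. Of 14 flavonoid genes 6 rose (7 adjusted over the list alone, camera adjusted p = 0.00081, and adjusted p = 0.132 with an estimated correlation), among them the synthesis enzymes FLS1 at 2.15 ± 0.24 and CHS at 2.08 ± 0.30. Expansins had 1 rise and 6 falls of 14 (2 and 6 adjusted over the list alone, camera adjusted p = 0.018, and adjusted p = 0.355 with an estimated correlation), and their median of 0.054 had the opposite sign to their mean and test. Clock genes fell in 6 of 20 cases (6 adjusted over the list alone, camera adjusted p = 0.0416, and adjusted p = 0.15 with an estimated correlation), with RVE1 at -0.98 ± 0.10 and CCA1 at -0.40 ± 0.07. XTH genes had 4 rises and 3 falls of 22 (4 and 3 adjusted over the list alone, camera adjusted p = 0.000206, and adjusted p = 0.0729 with an estimated correlation), with XTH19 at 4.49 ± 0.34. PHYA, PIF3 and PHYB rose by 2.32 ± 0.08, 1.59 ± 0.11 and 1.38 ± 0.08. Ethylene biosynthesis genes rose in 4 of 12 cases and fell in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.132 with an estimated correlation), with ACS8 at 4.48 ± 0.26 and ACS11 at -1.83 ± 0.23. Auxin transport (5 rises and 3 falls of 15; 7 and 3 adjusted over the list alone, camera adjusted p = 0.00636) and gibberellin genes (5 rises of 18; 6 and 1 fall adjusted over the list alone, camera adjusted p = 0.018) reached adjusted p = 0.15 and adjusted p = 0.0601 with an estimated correlation. Without high R/FR library 2 the count of changed genes was 2608.

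The same comparison in hypocotyl, the organ that elongates in shade, asks which genes respond there. At 15 min several shade markers and SAUR genes were higher, with no call among auxin biosynthesis genes. ATHB2 rose from 13.3 ± 0.665 to 126 ± 34.3 CPM (SD, n = 2), a log2 change of 3.24 ± 0.16, PIL1 by 3.09 ± 0.17, ATHB4 by 2.12 ± 0.24 and HFR1 by 1.3 ± 0.12. SAUR22 rose by 1.52 ± 0.22 and SAUR1 by 1.66 ± 0.26. In total 32 genes were higher and 4 lower, 17 of them by at least 2-fold. Of 17 shade markers 6 rose (9 adjusted over the list alone, camera adjusted p = 2.56e-51) and of 27 SAUR genes 11 rose (22 adjusted over the list alone; 2.56e-51). The 4 lower genes, named after their values were seen, were AT1G15405, AT2G31141 and the chloroplast-encoded ATCG00400 and ATCG00560. They stood at 11.2, 5.42, 3.2 and 3.34 CPM in high R/FR library 2 and at 2.29, 1.21, 0.53 and 0.706 CPM in high R/FR library 1. XTH15 (0.22 ± 0.18; adjusted p = 0.871), IAA19 (0.47 ± 0.25; 0.739) and IAA29 (1.28 ± 0.28; 0.0728) did not pass, and YUC8 and YUC9 had too few counts for a fold. Auxin biosynthesis genes had 0 of 8 called (1 fall adjusted over the list alone, camera adjusted p = 0.503), and 1430 genes had an unadjusted p below 0.05. Root markers had 0 of 6 members called (0 adjusted over the list alone) with a median of 1.158 and an upward camera test (adjusted p = 0.0118), which was lost at adjusted p = 0.747 with an estimated correlation. High R/FR library 2 had the most non-unique alignments of all libraries (39 per 100 gene counts), and without it 6 genes were called and SAUR22 and SAUR1 lost their calls (adjusted p = 0.0948 and 0.166). The count was 457 without high R/FR library 1, 17 without low R/FR library 1 and 202 without low R/FR library 3.

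At 45 min nearly every SAUR gene of the list was higher in hypocotyl, together with shade markers and Aux/IAA genes. SAUR28 rose by 3.54 ± 0.15, SAUR65 by 2.97 ± 0.15, SAUR64 by 2.62 ± 0.12 and SAUR29 by 2.37 ± 0.12, and 26 of 27 SAUR genes passed (26, and 1 fall, adjusted over the list alone, camera adjusted p = 3.05e-277). PIL1 rose by 5.37 ± 0.17, ATHB2 by 4.38 ± 0.16, HFR1 by 2.82 ± 0.12 and HAT3 by 1.94 ± 0.11, among 14 of 17 shade markers (16 adjusted over the list alone; 2.41e-135). IAA29, IAA5, IAA6, IAA19 and IAA2 rose by 3.04 ± 0.25, 3.12 ± 0.24, 3.04 ± 0.28, 2.83 ± 0.21 and 2.57 ± 0.15, among 11 of 27 Aux/IAA genes (13 adjusted over the list alone; 8.33e-29). RTFL18, a small peptide gene, rose by 5.28 ± 0.50, and AT1G78170 fell by 1.41 ± 0.16. In total 420 genes were higher and 246 lower, 215 by at least 2-fold. The auxin synthesis gene YUC3 rose by 2.90 ± 0.49, the only call of 8 in its list (1 adjusted over the list alone; 0.615). XTH15 stood at 0.25 ± 0.20 (adjusted p = 0.766), and YUC8 and YUC9 had too few counts for a fold. Brassinosteroid genes rose in 5 of 13 cases (5 adjusted over the list alone; 1.57e-08), with BR6OX2 at 1.27 ± 0.14 and the inactivating enzyme BAS1 at 2.32 ± 0.27. The gibberellin synthesis genes GA20OX1 and GA20OX2 rose by 2.07 ± 0.17 and 0.95 ± 0.16, in a list with 2 rises and 1 fall of 18 (2 and 2 adjusted over the list alone; 0.615). GH3 genes rose in 1 of 6 cases (3 adjusted over the list alone; 0.000213), GH3.5 at 1.66 ± 0.15. The expansins EXPA9 and EXPB1 rose by 1.21 ± 0.14 and 1.48 ± 0.20, with 2 rises and 1 fall of 14 (5 and 1 adjusted over the list alone; 0.000892, and adjusted p = 0.18 with an estimated correlation). The cyclin gene CYCD1;1 rose by 1.46 ± 0.12 as the only call among 16 cell cycle genes (1 adjusted over the list alone; 0.0278, and adjusted p = 0.126 with an estimated correlation). PHYB rose by 1.74 ± 0.08. Ethylene and auxin transport genes each had 3 rises, of 12 and 15 (3 and 3 adjusted over the list alone; both 0.00622), with adjusted p = 0.118 and adjusted p = 0.18 with an estimated correlation, and AUX1 stood at 0.59 ± 0.07. Vascular markers had 1 of 11 called (2 adjusted over the list alone; 0.00461, and adjusted p = 0.283 with an estimated correlation). The count of changed genes was 365 without high R/FR library 2 and 383 without low R/FR library 2.

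At 90 min the hypocotyl response covered 37.6% of the genes tested and reached ethylene synthesis and cell wall genes. All 27 listed SAUR genes and all 17 listed shade markers were higher, as were all 5 listed primary wall cellulose synthase genes and most listed XTH genes. ACS8, an ACC synthase with 0 counts in the high R/FR pair, was at least 1100-fold higher, ACS4 rose by 8.44 ± 0.34, and ACS5 was higher by a ratio of 286 (95% counting interval 78.9 to 2370). GH3.1 was higher by a ratio of 6080 (1090 to 240000). The largest falls were in OFP6 (-6.39 ± 0.44) and OFP18 (-4.91 ± 0.23), members of the ovate family, and in the nitrate reductase gene NIA1 (-4.41 ± 0.24). In total 3851 genes were higher and 3724 lower, 2114 by at least 2-fold. The split turned with RLE scaling (3698 and 3909) and with no low-count filter (3339 and 4050). SAUR genes rose in 27 of 27 cases (27 adjusted over the list alone, camera adjusted p = 5.6e-61), with SAUR68 at 7.02 ± 0.26, SAUR28 at 4.37 ± 0.15 and SAUR64 at 3.05 ± 0.12. Shade markers rose in 17 of 17 cases (17 adjusted over the list alone, camera adjusted p = 4.15e-28), PIL1 at 3.99 ± 0.17, FHL at 3.31 ± 0.16, ATHB2 at 2.15 ± 0.15 and HFR1 at 2.1 ± 0.12. Aux/IAA genes rose in 20 of 27 cases and fell in 2 (22 and 3 adjusted over the list alone, camera adjusted p = 8.75e-22). IAA6 rose by 8.03 ± 0.21, with IAA5 at 7.83 ± 0.24, IAA19 at 6.61 ± 0.24, IAA29 at 4.02 ± 0.25 and IAA28 at -1.66 ± 0.13. GH3 genes rose in 5 of 6 cases (5 adjusted over the list alone, camera adjusted p = 5.23e-14), with GH3.3 at 5.53 ± 0.18 and GH3.5 at 3.76 ± 0.17. XTH genes rose in 15 of 22 cases and fell in 4 (15 and 4 adjusted over the list alone, camera adjusted p = 2.54e-11). XTH19 rose by 6.93 ± 0.31, with XTH9 at 3.75 ± 0.16, XTH15 at 3.06 ± 0.17 and XTH32 at -1.76 ± 0.09. Ethylene biosynthesis genes rose in 5 of 12 cases and fell in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 2.66e-05). Cellulose synthase genes rose in 5 of 5 cases (5 adjusted over the list alone, camera adjusted p = 0.00738, and adjusted p = 0.431 with an estimated correlation), with CESA6 at 1.08 ± 0.09 and CESA3 at 0.65 ± 0.09. Expansins moved both ways, with 5 rises and 5 falls of 14 (5 and 5 adjusted over the list alone, camera adjusted p = 0.91), EXPB1 at 2.36 ± 0.17 and EXPB3 at -1.5 ± 0.11. The gibberellin synthesis genes GA20OX1, GA20OX2 and GA3OX1 rose by 3.42 ± 0.16, 2.75 ± 0.16 and 3.02 ± 0.21, in a list with 5 rises and 7 falls of 18 (5 and 7 adjusted over the list alone, camera adjusted p = 0.45). Auxin transport genes rose in 10 of 15 cases and fell in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.000914, and adjusted p = 0.105 with an estimated correlation). PIN3, PIN4 and PIN7 rose by 1.55 ± 0.13, 1.2 ± 0.09 and 1.14 ± 0.10. Of 22 light-harvesting and Rubisco small subunit genes 11 fell (11 adjusted over the list alone, camera adjusted p = 0.0292, and adjusted p = 0.682 with an estimated correlation), LHCB1.1 at -0.60 ± 0.09. In the jasmonate, touch and wound list 6 of 16 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.193), TCH2 at 2.79 ± 0.19 and the lipoxygenase LOX3 at -1.86 ± 0.21. YUC3 rose by 4.26 ± 0.40, YUC2 and YUC6 fell by 2.23 ± 0.45 and 1.1 ± 0.23, and YUC9 had too few counts for a fold. YUC8 stood at 1.52 ± 0.53 (adjusted p = 0.023) and lost its call without high R/FR library 1 (adjusted p = 0.189) or low R/FR library 1 (0.23).

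At 180 min the hypocotyl response covered 63.8% of the genes tested. The 5 listed primary wall cellulose synthase genes were higher, and all 22 listed light-harvesting and Rubisco small subunit genes were lower. XTH19 rose from 0.635 ± 0.488 to 338 ± 15.5 CPM (SD, n = 2), a log2 change of 8.99 ± 0.25, while XTH31 and XTH32 fell by 5.6 ± 0.18 and 3.11 ± 0.10. ACS11 and ACS4 rose by 4.44 ± 0.27 and 5.40 ± 0.30, and ACS8 and GH3.1 were higher by ratios of 619 (95% counting interval 211 to 3000) and 1360 (244 to 53800). AT5G35777 had 0 counts in the low R/FR pair and was at least 19.4-fold lower, and AT1G72910 fell by 5.36 ± 0.74. In total 6273 genes were higher and 6568 lower, 4501 by at least 2-fold. The 5 cellulose synthase genes rose in 5 of 5 cases (5 adjusted over the list alone, camera adjusted p = 0.00177, and adjusted p = 0.335 with an estimated correlation). CESA3 rose by 1.54 ± 0.09, with CESA1 at 1.47 ± 0.10 and CESA6 at 1.06 ± 0.09. Light-harvesting and Rubisco genes fell in 22 of 22 cases (22 adjusted over the list alone, camera adjusted p = 3.42e-06, and adjusted p = 0.335 with an estimated correlation), with LHCB4.3 at -1.71 ± 0.15, LHCB4.2 at -1.2 ± 0.08 and LHCA4 at -0.98 ± 0.08. SAUR genes rose in 24 of 27 cases (24 adjusted over the list alone, camera adjusted p = 3.66e-09, and adjusted p = 0.308 with an estimated correlation), with SAUR10 at 4.81 ± 0.27 and SAUR68 at 4.37 ± 0.21. Shade markers rose in 16 of 17 cases and fell in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 3.66e-09, and adjusted p = 0.202 with an estimated correlation). PIL1 rose by 3.28 ± 0.17, with ATHB2 at 2.78 ± 0.15, HFR1 at 2.1 ± 0.12 and the cytokinin oxidase CKX6 at -1.12 ± 0.18. Aux/IAA genes rose in 15 of 27 cases and fell in 4 (15 and 4 adjusted over the list alone, camera adjusted p = 0.000694, and adjusted p = 0.308 with an estimated correlation). IAA6 rose by 5.77 ± 0.18, with IAA19 at 4.69 ± 0.22 and IAA29 at 2.6 ± 0.23. Ethylene genes rose in 7 of 12 cases and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00214, and adjusted p = 0.202 with an estimated correlation). GH3 genes rose in 4 of 6 cases and fell in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0294, and adjusted p = 0.308 with an estimated correlation). XTH genes rose in 15 of 22 cases and fell in 4 (15 and 4 adjusted over the list alone, camera adjusted p = 0.0709), with XTH15 at 2.1 ± 0.16. Expansins rose in 7 of 14 cases and fell in 4 (7 and 4 adjusted over the list alone, camera adjusted p = 0.594), EXPA11 at 2.01 ± 0.12, EXPA9 at 1.94 ± 0.14 and EXPB3 at -2.99 ± 0.11. Brassinosteroid genes rose in 9 of 13 cases and fell in 4 (9 and 4 adjusted over the list alone, camera adjusted p = 0.433), with DWF1 and DWF5 at 0.95 ± 0.06 and 0.56 ± 0.06 and ROT3 at -1.63 ± 0.11. YUC8 rose by 4.3 ± 0.54, and YUC9 stood at a ratio of 3.27 (95% counting interval 0.841 to 18.5; adjusted p = 0.0991). Clock genes rose in 6 of 20 cases and fell in 8 (6 and 8 adjusted over the list alone, camera adjusted p = 0.594), with RVE1 at -1.74 ± 0.09 and LUX at 1.77 ± 0.15. Heat shock genes rose in 4 of 7 cases and fell in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.486), with HSP101 at 0.94 ± 0.12. Of 16 cell cycle genes 1 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.886). Of 8 carbon starvation genes 1 rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.433). Markers of other tissues moved too: root markers fell in 5 of 6 cases (5 adjusted over the list alone, camera adjusted p = 0.481), with CASP2, a Casparian strip protein of the root endodermis, at -3.87 ± 0.66. Vascular markers fell in 8 of 11 cases (8 adjusted over the list alone, camera adjusted p = 0.278), with the sucrose transporter SUC2 at -0.68 ± 0.11. Shoot apex markers fell in 2 of 5 cases (2 adjusted over the list alone, camera adjusted p = 0.486), the homeobox genes KNAT2 and KNAT1 at -1.21 ± 0.17 and -0.70 ± 0.15. Stomatal lineage markers had 1 rise and 1 fall of 8 (1 and 1 adjusted over the list alone, camera adjusted p = 0.701), and the salicylate defence list had 0 of 2 called (0 adjusted over the list alone, camera adjusted p = 0.95). Without low R/FR library 1 the calls were 5027 higher and 6747 lower, with a shift of -0.114 in the median log2 change of all genes.

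**Figure D2:**
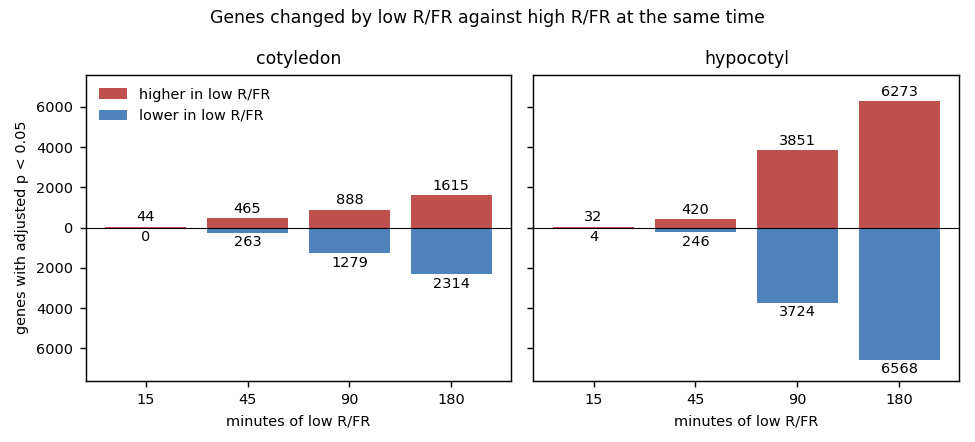
Number of genes with adjusted p < 0.05 (vertical axis; higher in low R/FR above 0, lower below) against minutes of low R/FR in cotyledon and hypocotyl, from 2 libraries per light and time. The counts grew from 44 higher and 0 lower to 1615 and 2314 in cotyledon, and from 32 and 4 to 6273 and 6568 in hypocotyl.

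**Figure D3:**
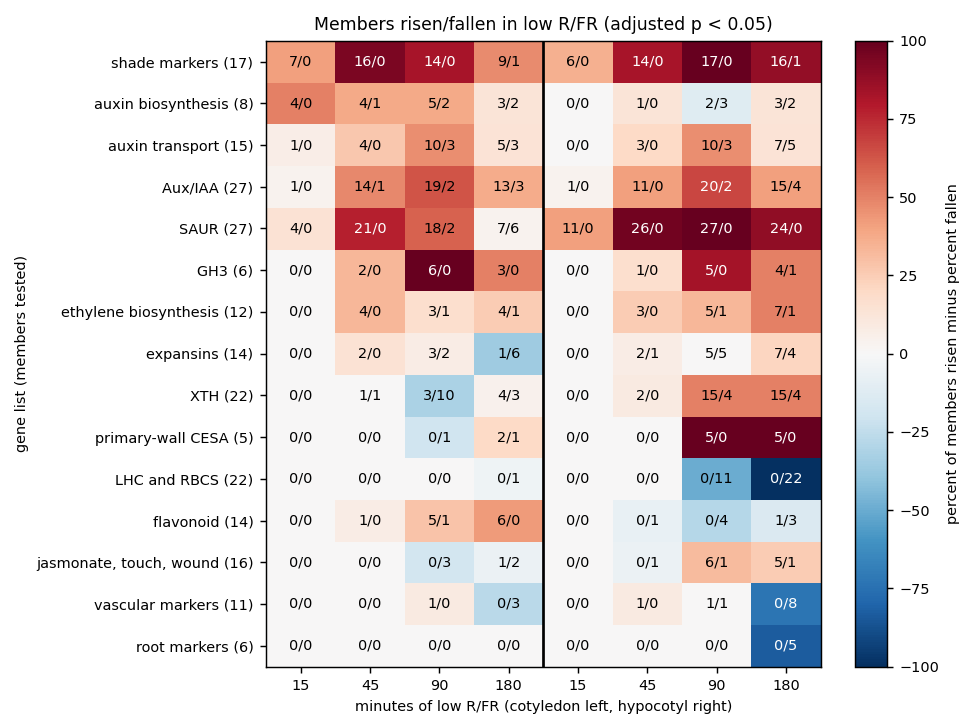
Members of 15 gene lists that rose and fell in low R/FR (numbers in cells) with the percent risen minus the percent fallen as colour, by minutes in cotyledon (left) and hypocotyl (right). SAUR genes rose in 27 of 27 cases in hypocotyl at 90 min, and light-harvesting and Rubisco small subunit genes (LHC and RBCS) fell in 22 of 22 at 180 min.

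Calls were compared between successive times within an organ to ask how far early responses persisted. In cotyledon 43 of the 44 genes higher at 15 min were also higher at 45 min (1.02 if the calls were independent), and in hypocotyl 31 of 32 (0.668). Of the genes higher at 15 min in cotyledon, 31 were higher at 180 min (3.53 if independent) and 3 lower (5.06), and in hypocotyl 23 were higher (9.97) and 4 lower (10.4). The genes that were higher first and lower later, named after their values were seen, were ATL4, PRE1 and P1R1 in cotyledon and LSH6, HBI1, AT2G36026 and AT4G28240 in hypocotyl. PRE1 went from 1.16 at 15 min to -1.79 at 180 min in cotyledon, and HBI1, which also encodes a basic helix-loop-helix factor, from 0.45 to -0.51 in hypocotyl. Between organs at the same time, 15 genes were higher in both at 15 min (0.07 if independent) and 230 at 45 min (9.7), with 70 lower in both (3.21). At 90 min 484 genes were higher in both (170 if independent) and 626 lower in both (237), and at 180 min 913 (503) and 1466 (755).

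The difference between the hypocotyl and the cotyledon response was tested directly to ask where the organs answer low R/FR differently. At 15 min the response of ATHB4 was weaker in hypocotyl by 2.83 ± 0.45 and that of ATHB2 by 1.5 ± 0.24, and YUC9 (adjusted p = 0.0182) had 3 counts in the low R/FR hypocotyl pair beside 411 in cotyledon. These were the 3 genes called, all lower in hypocotyl, and limma-voom called 1. The count fell to 0 without hypocotyl high R/FR library 2 or cotyledon high R/FR library 2 and to 1 without cotyledon high R/FR library 1 or low R/FR library 1. It was 68 without hypocotyl high R/FR library 1, 6 without hypocotyl low R/FR library 1 and 5 without hypocotyl low R/FR library 3. At 45 min 59 genes had a higher and 81 a lower response in hypocotyl, 78 by at least 2-fold. With the replicate numbers as blocks across organs, 99 had a higher and 138 a lower response. CKX5 differed by -5.71 ± 0.43, GH3.3 by -4.59 ± 0.30 and GH3.6 by -2.78 ± 0.32, and AT1G06360 and AT5G54145 by 2.21 ± 0.37 and 2.07 ± 0.32. ST2A (adjusted p = 0.00054) had 3 counts in the high R/FR cotyledon pair against 310 in low R/FR, and 62 against 252 in hypocotyl. AT5G45850 differed by 2.02 ± 0.45, a call that was lost with limma-voom and without any 1 of several libraries. Shade markers had 1 higher and 4 lower of 17 (2 and 11 adjusted over the list alone, camera adjusted p = 7.98e-20) and GH3 genes 2 lower of 6 (1 higher and 2 lower adjusted over the list alone; 1.43e-13). SAUR genes had 7 higher of 27 (11, and 1 lower, adjusted over the list alone; 4.68e-14, and adjusted p = 0.18 with an estimated correlation), SAUR14 at 1.21 ± 0.17. The 3 genes called in opposite directions in the organs, with the difference also called, were AT1G52750, LYK4 and ZPR1, named after their values were seen. The count at 45 min was 475 without cotyledon low R/FR library 1, 92 and 87 without cotyledon high R/FR library 1 and 2, and 90 without hypocotyl high R/FR library 2.

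At 90 min the hypocotyl response was higher for most of the listed SAUR and XTH genes. In total 2465 genes had a higher and 1835 a lower response in hypocotyl, 1699 by at least 2-fold, and with no low-count filter 2067 were higher and 2086 lower. PHI-1, a gene of the EXORDIUM-like family, differed by 7.94 ± 0.45, AT3G55840 by 7.69 ± 0.56 and IAA6 by 6.32 ± 0.34. SAUR genes were higher in 25 of 27 cases (25 adjusted over the list alone, camera adjusted p = 8.78e-25), SAUR15 at 4.13 ± 0.29. XTH genes were higher in 15 and lower in 2 of 22 (15 and 2 adjusted over the list alone; 9.12e-15), XTH9 at 4.26 ± 0.21. Cellulose synthase genes were higher in 5 of 5 cases (5 adjusted over the list alone; 0.000134, and adjusted p = 0.219 with an estimated correlation), CESA6 at 1.32 ± 0.12. Aux/IAA genes were higher in 12 cases and lower in 3 of 27 (12 and 3 adjusted over the list alone; 0.000128, and adjusted p = 0.219 with an estimated correlation). Ethylene genes were higher in 6 of 12 cases (6 adjusted over the list alone; 0.00194, and adjusted p = 0.111 with an estimated correlation), among them ACS8 (adjusted p = 0.00102), which went from 0 to 3210 counts in hypocotyl and from 100 to 3754 in cotyledon. BR6OX1 differed by 3.69 ± 0.36. OFP6 differed by -5.63 ± 0.68, and GolS2, a galactinol synthase (adjusted p = 0.000238), went from 456 to 250 counts in hypocotyl and from 0 to 13 in cotyledon. AT3G21330 differed by -5.89 ± 1.28 and lost its call without hypocotyl high R/FR library 1 (-4.27; adjusted p = 0.337). At 180 min 4768 genes had a higher and 4583 a lower response in hypocotyl, 3572 by at least 2-fold. The split turned with RLE scaling (4390 higher and 5038 lower) and with no low-count filter (3654 and 5472). XTH15 differed by -5.96 ± 0.28 and XTH31 by -5.94 ± 0.23, ACS11 by 6.26 ± 0.36, PRE1 by 4.32 ± 0.34, EXPA5 by 2.50 ± 0.18 and CESA3 by 1.26 ± 0.13. SAUR genes were higher in 20 cases and lower in 1 of 27 (20 and 1 adjusted over the list alone; 1.74e-06) and photosynthesis genes lower in 17 of 22 (18 adjusted over the list alone; 1.26e-05), both at adjusted p = 0.433 with an estimated correlation. Cellulose synthase genes were higher in 5 of 5 (5 adjusted over the list alone; 0.00148, and adjusted p = 0.433 with an estimated correlation). Flavonoid genes were lower in 7 of 14 (7 adjusted over the list alone; 0.0358, and adjusted p = 0.511 with an estimated correlation). AT5G35777 (adjusted p = 2.47e-05) went from 57 to 0 counts in hypocotyl and from 1082 to 398 in cotyledon, and ARPN, a plantacyanin (adjusted p = 0.00169), from 511 to 152 in hypocotyl and from 0 to 4 in cotyledon. GH3.1 (adjusted p = 0.00205) went from 1 to 1388 counts in hypocotyl and from 4 to 0 in cotyledon, and its call was lost without cotyledon high R/FR library 2 (adjusted p = 1). TGG2, a myrosinase (adjusted p = 0.00627), and AT3G22142 (0.0196) had 253 and 55 counts in the low R/FR hypocotyl pair, all from library 1, and without that library both had an adjusted p of 1. Genes called in opposite directions in the organs, with the difference also called, numbered 445 at 90 min and 753 at 180 min. If the calls were independent, 245 and 164 genes (higher and lower in hypocotyl) would be called in opposite directions at 90 min, where 304 and 141 were, and 721 and 527 at 180 min, where 395 and 358 were. Leaving out 1 hypocotyl library of 180 min shifted the median difference of all genes by -0.118 to -0.144.

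**Figure D4:**
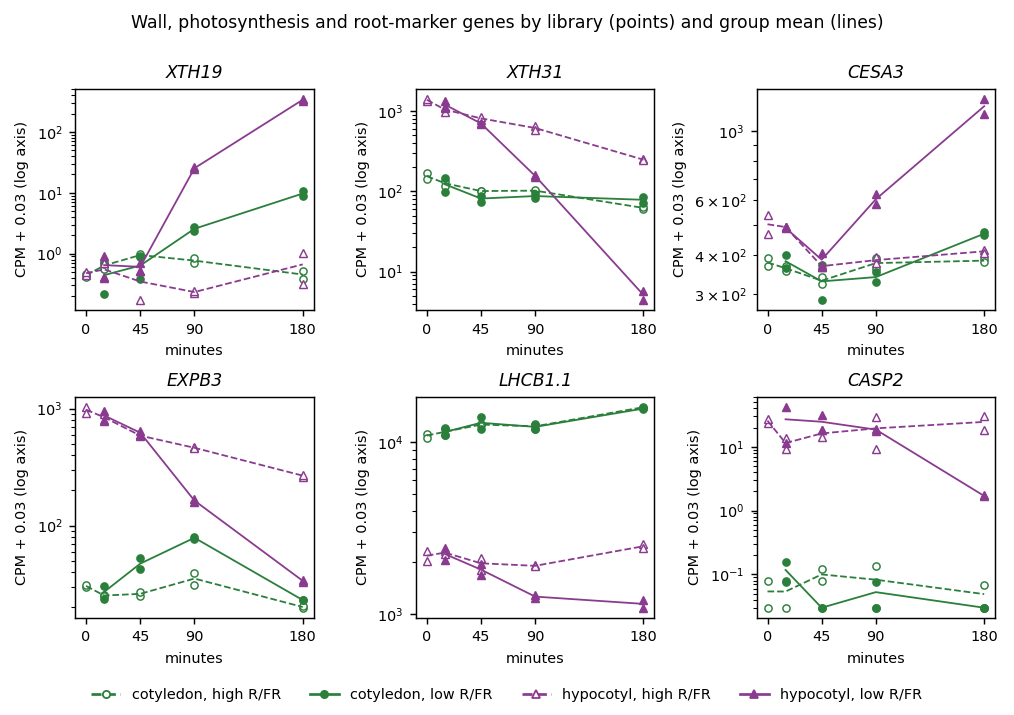
CPM (plus 0.03, log axis) of wall genes XTH19, XTH31, CESA3 and EXPB3, the light-harvesting gene LHCB1.1 and the root marker CASP2 against minutes, with points for libraries, lines for means of 2, open and dashed for high R/FR, filled and solid for low R/FR. In hypocotyl XTH19 reached a mean of 338 CPM at 180 min of low R/FR against 0.635 in high R/FR, and CASP2 stood at 1.67 against 24.5 CPM.

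Libraries of 180 and 0 min in high R/FR were compared to ask how far transcripts change over the same hours without a change of light. Single clock, flavonoid and heat shock genes changed in both organs, and none of these lists passed with an estimated correlation in either organ. LHY, a morning clock gene, fell by 3.2 ± 0.08 in cotyledon and 2.1 ± 0.07 in hypocotyl, and PRR7, a later clock gene, rose by 2.28 ± 0.13 and 2.4 ± 0.13. CHS, the first enzyme of flavonoid synthesis, fell by 4.69 ± 0.32 and 4.02 ± 0.43, and F3H changed by -2.93 ± 0.13 and -2.64 ± 0.13. In cotyledon 6468 genes were higher and 4721 lower at 180 min, 3869 by at least 2-fold, beside a median log2 change of 0.1085 over all genes. With the organ's own 18 libraries 5277 were higher and 5534 lower. In hypocotyl 4428 were higher and 4616 lower, 2054 by at least 2-fold. The largest changes in cotyledon included AT3G62550 at 5.54 ± 0.23 and AT1G26790 at -7.09 ± 0.22, and RTFL21 and YUC9, with 0 counts at 0 min, were at least 7.06-fold and 5.65-fold higher. In hypocotyl XTH33 rose by 5.21 ± 0.49, AT1G56300 by 5.25 ± 0.37, and the early light-inducible gene ELIP1 and AT5G39670 changed by -4.34 ± 0.35 and -4.06 ± 0.54. ACS4, at 0 counts at 0 min in hypocotyl, was at least 7.34-fold higher. Flavonoid genes fell in 10 of 14 cases in cotyledon (10 adjusted over the list alone, camera adjusted p = 2.41e-05, and adjusted p = 0.264 with an estimated correlation). In hypocotyl 10 fell and 1 rose (10 and 1 adjusted over the list alone; 1.62e-07, and adjusted p = 0.0847 with an estimated correlation). Heat shock genes fell in 6 cases and rose in 1 of 7 in cotyledon (6 and 1 adjusted over the list alone; 0.000345, and adjusted p = 0.264 with an estimated correlation), HSP101 at -2.27 ± 0.14. In hypocotyl they fell in 4 and rose in 1 (5 and 1 adjusted over the list alone; 0.0257, and adjusted p = 0.366 with an estimated correlation). Clock genes rose in 10 cases and fell in 6 of 20 in both organs (10 and 6, and 10 and 7, adjusted over the list alone; 0.853 and 0.159). Photosynthesis genes rose in 17 of 22 cases in cotyledon and fell in 2 (17 and 2 adjusted over the list alone; 0.000357, and adjusted p = 0.622 with an estimated correlation), LHCB1.2 at 1.11 ± 0.09. Carbon starvation genes rose in 5 of 8 cases in cotyledon and in 6 in hypocotyl (6 and 6 adjusted over the list alone; 0.0235 and 0.0412, with adjusted p = 0.565 and adjusted p = 0.366 with an estimated correlation), among them DIN4 at 1.73 ± 0.12 and 0.81 ± 0.11. In hypocotyl SAUR genes rose in 21 of 27 cases (22 adjusted over the list alone; 2.65e-06) and shade markers in 14 of 17 (14 adjusted over the list alone; 5.25e-07), with adjusted p = 0.366 and adjusted p = 0.246 with an estimated correlation, SAUR1 at 2.91 ± 0.28 and FHL at 2.43 ± 0.20. XTH genes fell in 13 of 22 cases in cotyledon and rose in 4 (13 and 4 adjusted over the list alone; 0.0065, and adjusted p = 0.359 with an estimated correlation), XTH33 at -3.05 ± 0.30 there. In cotyledon the brassinosteroid synthesis genes CPD and DWF4 rose by 1.55 ± 0.08 and 1.4 ± 0.10.

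Hypocotyl and cotyledon were compared over the 20 high R/FR libraries, with time as a term, to ask how the organs differ without low R/FR; values are log2 hypocotyl over cotyledon. Hypocotyls held more transcript of shoot apex and auxin-conjugation genes, and cotyledons more of photosynthesis and stomatal genes. KNAT1, a homeobox gene of the shoot meristem, was higher in hypocotyl by 10.67 ± 0.16, as were MLP168 by 11.50 ± 0.14, UCC1, a copper-binding uclacyanin, by 11.20 ± 0.27, ST4C, a sulfotransferase, by 10.85 ± 0.17 and AT1G30750 by 10.65 ± 0.36. DOT3, a protein with an NPH3 domain, was lower in hypocotyl (-12.63 ± 0.15), as were TGG2 (-12.61 ± 0.23), AT3G05730 (-12.36 ± 0.24), AT3G16660 (-12.01 ± 0.20) and AT3G16670 (-11.92 ± 0.17). Of 19825 genes 8084 were higher and 7813 lower in hypocotyl, 6229 by at least 2-fold. The 5 shoot apex markers were all higher (5 adjusted over the list alone, camera adjusted p = 1.34e-12), KNAT6 at 6.79 ± 0.11 and STM at 7.18 ± 0.32. Root markers were higher in 5 of 6 cases (5 adjusted over the list alone; 0.00458, and adjusted p = 0.375 with an estimated correlation), CASP1 at 10.09 ± 0.41. Photosynthesis genes were lower in 21 of 22 cases (21 adjusted over the list alone; 4.60e-21), LHCB1.2 at -2.54 ± 0.04 and LHCA1 at -1.92 ± 0.03. Stomatal lineage genes were lower in 7 of 8 cases (7 adjusted over the list alone; 7.32e-08), KAT1 at -6.06 ± 0.10, FAMA at -4.26 ± 0.11 and SPCH at -5.05 ± 0.16. GH3 genes were higher in 5 of 5 cases (5 adjusted over the list alone; 1.06e-05), GH3.6 at 8.01 ± 0.18 and GH3.17 at 4.06 ± 0.10. Auxin biosynthesis genes were lower in 6 cases and higher in 1 of 8 (6 and 1 adjusted over the list alone; 0.00579, and adjusted p = 0.0982 with an estimated correlation). YUC8 stood at -5.85 ± 0.25, YUC2 at -4.19 ± 0.11 and TAA1 at -3.94 ± 0.13. Auxin transport genes were higher in 12 cases and lower in 3 of 15 (12 and 3 adjusted over the list alone; 0.0018, and adjusted p = 0.0865 with an estimated correlation), with ABCB19 at 1.85 ± 0.05. LOX2, a chloroplast lipoxygenase, was lower by 11.02 ± 0.20 and CHS by 4.03 ± 0.16, while PIL1 and XTH15 were higher by 4.57 ± 0.17 and 2.88 ± 0.17. When the test asked for a difference beyond 2-fold, 2703 genes were higher and 2421 lower.

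The calls were set beside the authors' deposited tables of low against high R/FR, which hold their own p-values per gene. In cotyledon the authors' deposited tables marked 210, 935, 1906 and 2965 genes at 15, 45, 90 and 180 min, and 40, 685, 1797 and 2855 of them were called here in the same direction. In hypocotyl the authors' deposited tables marked 448, 951, 6291 and 11241 genes, of which 34, 614, 6181 and 11122 were called here in the same direction. Those marks rest on an adjustment over the 4 times together. Adjusted within each time, the p-values of the authors' deposited tables gave 54, 736, 2016 and 3826 genes in cotyledon and 23, 422, 6727 and 12338 in hypocotyl. No gene was called in opposite directions, and log2 changes in the authors' deposited tables correlated across genes with those computed here at r of 0.883 to 0.991; genes are not independent replicates.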

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

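Of the tests in this part, those of scaling between all libraries, shoot apex tissue, root tissue (both parts), light exposure of the number 3 plates, scaling between the number 1 and number 3 libraries, cotyledon carry-over into the TGG2 library and a fixed TGG2 share of TGG1 were chosen only after the result was seen.

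The hypocotyl changed in far more genes than the cotyledon after 180 min in low R/FR: 12841 genes were called, and the difference between the organs' responses was called for 9351 of 20126 (edgeR). RLE scaling and the hypocotyl libraries alone gave 12754 calls at the lower, so the choice among these scalings did not set the count. Each assumes, as TMM over all libraries does, that most genes do not change, so a scaling error common to them stayed open. Dominance of a few genes was argued against by 12706 calls without the 100 most abundant genes (12742 with them counted). GC content or gene length was argued against by 12782 calls with the GC trend of each library removed (13022 with the length trend, 12830 with neither). Cotyledon carry-over was argued against by 42 cotyledon genes with a median of at most 0.642% of their mean cotyledon level at 180 min in both lights in any of the 4 libraries. A smaller share of shoot apex as the only cause was argued against by its 3 markers, which lay 6.79 SE apart (0.11 to -1.21). As a part of the fall of KNAT2 and KNAT1 it stayed open, since responses of single genes on top of it would also spread the markers. A smaller share of root tissue would raise the genes of other tissues together. As the only cause it was argued against by 22 of 22 light-harvesting and Rubisco genes that fell while 2120 genes rose at least 2-fold. It stayed open for the fall of the 5 root markers, which lay 2.84 SE apart (-1.59 to -3.87). As a part of the fall of other genes expressed in root it was not tested. A response of the hypocotyl itself, which the design names, is a hypothesis that was found and examined on the same data. A part played by tissue shares beside it was not excluded.

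At 15 min in low R/FR, genes up at least 2-fold at 45 min were lower in the libraries numbered 3 than in those numbered 1, with a median log2 ratio of number 1 over number 3 of 0.14 in cotyledon (142 of 201 genes above the median of all genes) and 0.51 in hypocotyl (147 of 159). The same genes stood at 0.05 and 0 between the high R/FR libraries 1 and 2, and the 25 and 21 genes down at 45 min at 0.04 and 0.1, where a weaker response would give values under 0. A scaling factor between libraries was argued against, since it moves all genes alike and at least 70.6% of the rising genes lay above the median of all genes. A shorter or weaker exposure of the number 3 plates stayed open at 0.14, because the cotyledon shift was small and the falling genes were few, and so did a library batch, with a larger spread in groups holding a number 3 library (0.228 against 0.202; exact one-sided permutation p of 0.201 over 3060 groupings). No biological explanation was tested.

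TGG2 had 253 counts (7.12 CPM) in hypocotyl library 1 of 180 min in low R/FR and 8 counts in the other 17 hypocotyl libraries together. A fixed share of TGG1 reads was argued against, since the library with the highest TGG1 among the others had 0 TGG2 counts beside 6048 of TGG1, a ratio of 0 to that in this library (4374 TGG1 counts). Cotyledon carry-over into this library stayed open, because TGG2 reached 5.67% of its level in low R/FR cotyledons of 180 min and the 41 other cotyledon genes a median of 0.981% and a 90th percentile of 3.66%, with 2 of them at or above TGG2. Reads of TGG1 stayed open in part, at 123 CPM of TGG1 in this library and 165 CPM in the highest other. No biological explanation was tested.

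The difference between the organs' responses to low R/FR was called for 3 genes at 15 min, 140 at 45 min, 4300 at 90 min and 9351 at 180 min (edgeR, response of hypocotyl minus that of cotyledon). At 15 min these were YUC9 (adjusted p 0.0182), ATHB4 (log2 difference -2.83) and ATHB2 (-1.50). The YUC9 call was lost without hypocotyl high R/FR library 1 (adjusted p 0.0756) or 2 (0.179) or cotyledon high R/FR library 2 (0.14). Those of ATHB4 and ATHB2 were lost without cotyledon high R/FR library 1 (0.403 and 0.23) or 2 (0.323 and 0.285), hypocotyl high R/FR library 2 (0.229 and 0.0651) or cotyledon low R/FR library 1 (0.0671 and 0.0783), and with limma-voom (0.916 and 0.246).

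At 45 min CKX5 (-5.71), GH3.3 (-4.59), ST2A (adjusted p 0.00054) and GH3.6 (-2.78) had a lower response in hypocotyl, where GH3.3 and GH3.6 were not called. SAUR14 (1.21) and AT1G06360 (2.21) were called as higher in hypocotyl and not in cotyledon, and AT5G54145 (2.07) and AT5G45850 (2.02) as lower in cotyledon and not in hypocotyl. The AT5G45850 call was lost without cotyledon high R/FR library 1 (0.125) or 2 (0.0563), hypocotyl low R/FR library 1 (0.0673) or cotyledon low R/FR library 2 (0.397), and with limma-voom (0.0739). At 90 min the differences were 7.94 for PHI-1, 7.69 for AT3G55840, 6.32 for IAA6, 4.13 for SAUR15, 4.26 for XTH9, 1.32 for CESA6, 3.69 for BR6OX1, -5.89 for AT3G21330 and -5.63 for OFP6, with ACS8 at an adjusted p of 0.00102 and GolS2 at 0.000238. AT3G21330 was no longer called without hypocotyl high R/FR library 1 (-4.27, adjusted p 0.337).

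At 180 min they were 6.26 for ACS11, 4.32 for PRE1, 1.26 for CESA3, 2.50 for EXPA5, -5.96 for XTH15 and -5.94 for XTH31. Genes with few counts in a group had adjusted p of 0.00205 (GH3.1), 0.00627 (TGG2), 0.0196 (AT3G22142), 2.47e-05 (AT5G35777) and 0.00169 (ARPN). The GH3.1 call was lost without cotyledon high R/FR library 2 (adjusted p 1), and those of TGG2 and AT3G22142 without hypocotyl low R/FR library 1 (adjusted p 1 for both) and with limma-voom (0.314 and 0.208). AT3G22142 was also not called without hypocotyl high R/FR library 2 (0.0874) or 3 (0.0694). Between 90 and 180 min the hypocotyl response of ATHB2 differed by 0.64 and that of ATHB4 by 0.82, with edgeR adjusted p of 0.0141 and 0.08 over all genes (0.00815 and 0.0482 over 10 tests chosen afterwards).

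Outside the gene counts, non-unique alignments stood at 16 per 100 gene counts in cotyledon library 2 of 45 min in low R/FR and at 20.2 in cotyledon library 2 of 90 min in low R/FR, above the highest high R/FR cotyledon library (14.4). In hypocotyl the highest was a high R/FR library (39), and 0 low R/FR libraries lay above it. No outlier test was run within groups of 2 libraries. The pairs that differed most were hypocotyl at 15 min in high R/FR (chi-square per degree of freedom 20.16) and cotyledon at 45 min in low R/FR (16.64).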

How the results depend on the processing

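Of the tests in this part, the fits without the library with the most non-unique alignments and without the 4 libraries numbered 3 were chosen only after the results were seen.

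All 15 counts of called genes stayed within 1.5 times the reported count with RLE size factors. Among 15 counts each, 2 grew by more with no low-count filter, 1 with DESeq2 and 2 without the libraries numbered 3, while 1 shrank with limma-voom and 2 without the library with the most non-unique alignments (hypocotyl, high R/FR, 15 min, library 2). For low R/FR at 15 min in hypocotyl (36 genes), the counts were 74 with no filter, 94 with DESeq2, 14 with the organ's own 18 libraries, 6 without the most non-unique library and 179 without the libraries numbered 3. The difference between organs at 15 min (3 genes) became 7 with no filter, 1 with limma-voom and 5 without the libraries numbered 3. Its reported test had 747 genes at an unadjusted p under 0.05, fewer than chance would give. A minimum 2-fold test between the organs called 5124 of the 15897 genes. With estimated correlations, 42 of the 110 calls of gene lists among 375 list and comparison pairs were made, all among the 110. Leaving out each library in turn changed 24 of 92 counts by more than 1.5 times, 17 of them downward; the lone sample of a group was then assumed to vary like the other groups. The counts ran from 25 to 47 at 15 min in cotyledon (44 reported; lowest without high R/FR library 1, and 26 without high R/FR library 2 or low R/FR library 1), 433 to 2132 at 45 min (728; without high R/FR library 1 and low R/FR library 1, and 471 without low R/FR library 2) and 2608 to 2692 at 180 min (3929 reported, lowest without high R/FR library 2). In hypocotyl they ran from 6 to 457 at 15 min (lowest without high R/FR library 2, highest without high R/FR library 1, with 17 without low R/FR library 1 and 202 without low R/FR library 3) and from 365 to 604 at 45 min (666; lowest without high R/FR library 2, and 383 without low R/FR library 2). The difference between organs ran from 0 (cotyledon or hypocotyl high R/FR library 2 left out) to 68 (hypocotyl high R/FR library 1) at 15 min and from 87 (cotyledon high R/FR library 2) to 475 (cotyledon low R/FR library 1) at 45 min (140 reported), with 92 without cotyledon high R/FR library 1 and 90 without hypocotyl high R/FR library 2. Without cotyledon low R/FR library 1 the genes at 45 min were 926 higher and 1206 lower. The split of calls at 180 min in cotyledon was 1988 higher and 1805 lower with the organ's own 18 libraries (52.4% higher against 41.1%), 2017 and 2008 without the most non-unique library and 1941 and 1935 without the libraries numbered 3. In hypocotyl it moved toward falls with any 180 min library left out. For the difference between organs at 180 min (4768 and 4583 reported) it was 4390 and 5038 with RLE, 4199 and 4834 with DESeq2, 3654 and 5472 with no filter, 3849 and 5754 without the most non-unique library, and 3141 and 4697 without the libraries numbered 3. At 90 min (2465 and 1835) it was 2067 and 2086 with no filter, 2181 and 2312 without the most non-unique library, and 2147 and 2206 without the libraries numbered 3. The majority also turned for low R/FR at 90 min in hypocotyl (3851 and 3724) with RLE (3698 and 3909), DESeq2 (3505 and 3653) and no filter (3339 and 4050), and without the most non-unique library (3476 and 4389) or the libraries numbered 3 (3412 and 4293). It turned at 180 min in hypocotyl with the organ's own 18 libraries (6391 and 6363) and for 180 against 0 min in cotyledon with the same setting (5277 and 5534), so none of these splits gives a direction of the whole response. Of 1175 pairs of a named gene and a comparison, 990 had the same call under every alternative; over 16615 values, 486 were weaker, 68 stronger and 0 reversed. Among the panel, PIL1 at 15 min in cotyledon was called with RLE (adjusted p 0.0494), DESeq2 (0.00882) and the number block (0.027). With no filter, the medians of the Aux/IAA list at 15 min (0.084) and of auxin synthesis at 180 min (-0.11) in cotyledon became 0. Samples of the 2 organs with the same number correlated at 0.08 to 0.32 over 9 sets (7 over 0.1) and those of the 2 lights at -0.23 to 0.17 over 8 sets (2 over 0.1), so the numbers were not taken as pairs. All 9 sets of the organs were above 0, and the labels leave a plate shared by the organs open. With the replicate number as a block across lights, 70 genes were called at 15 min in cotyledon. With the replicate block across organs, the difference between organs was called for 7 genes at 15 min, 237 at 45 min and 7236 at 180 min (9351 reported), and the blocks moved that last count and the other 11 fitted with them by less than 1.5 times. For these changes the cause was not tested.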

Other observations

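Of the tests in this part, those of the gene families and of the second rise were chosen only after the result was seen. After 180 min in low R/FR, most hypocotyl genes of protein synthesis that changed were higher, but as families most of them did not pass with the estimated correlation. Of 21 families looked at, taken from the authors' deposited descriptions, ribosomal protein genes rose in 242 and fell in 44 of 336 (camera adjusted p 3.86e-09; 0.315 with the estimated correlation). Translation initiation factors rose in 22 and fell in 2 of 31 (0.00016; 0.181), proteasome genes rose in 23 and fell in 3 of 32 (0.00109; 0.236), vesicle coat genes rose in 8 of 9 (9.48e-05; 0.145) and translocon genes in 4 of 6 (0.00016; 0.0128). Tubulins and kinesins rose in 23 and fell in 7 of 40 (2.59e-08; 0.0201), among them TUA2 (log2 fold change 1.73), TUA4 (1.62) and TUB5 (1.47), and arabinogalactan proteins rose in 28 and fell in 4 of 44 (6.06e-06; 0.236), among them AGP21 (2.48) and FLA9 (2.05). Other families of the wall did not rise together: cellulose synthase genes rose in 8 and fell in 11 of 20 (0.317; 0.561), pectin genes rose in 13 and fell in 13 of 42 (0.495; 0.679), and lignin and laccase genes rose in 1 and fell in 5 of 10 (0.384; 0.561). The genes named here were singled out after their values were seen.

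Cytochrome P450 genes went the other way in hypocotyl, with 13 higher and 63 lower of 119 (camera adjusted p 7.78e-07; 0.0385 with the estimated correlation). CYP71B2 fell by 3.00 and CYP71B7 by 2.33 on the log2 scale, while CYP86A4 (4.92) and CYP86A7 (2.91) rose; they too were chosen after their values were seen. Genes described as chloroplast fell more often than they rose (163 and 80 of 368; 0.00581 and 0.315), as did lipid transfer genes (6 and 2 of 11; 0.0386 and 0.315), and sugar genes rose more often (53 and 33 of 109; 0.0143 and 0.0963). In cotyledon at the same time, ribosomal protein genes rose in 56 and fell in 1 of 336 (0.000266; 0.887) and cellulose synthase genes fell in 8 and rose in 1 of 20 (0.00151; 0.34). At 90 min in cotyledon the cellulose synthase genes fell in 8 and rose in 0 of 20 (2e-07; 0.0187). With the estimated correlation, tubulins and kinesins, translocon and cytochrome P450 genes in hypocotyl and cellulose synthase genes in cotyledon at 90 min had an adjusted p under 0.05, and the other families named here did not.

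Among genes whose response differed between the organs, the larger response lay in cotyledon for 3 of 3 at 15 min and 95 of 140 at 45 min, and in hypocotyl for 3552 of 4300 at 90 min and 8311 of 9351 at 180 min. The change at 180 min in hypocotyl was not a reversal of the change from 0 to 90 min in high R/FR, which used other libraries. Across 16261 genes the changes correlated at 0.12 (Pearson, with Spearman at 0.03). A reversal of changes that arose after 90 min was not tested. Of 5 related homeodomain-leucine zipper genes, 2 responded more at 180 than at 90 min in hypocotyl, ATHB2 (0.64, adjusted p 0.00815 over the 10 tests) and ATHB4 (0.82, 0.0482, but 0.08 over all genes), while HAT2 (-1.98) and HAT3 (-0.51) responded less and 0 of the 5 responded more in cotyledon. A later second rise shared by all 5 genes was argued against by the lower HAT2 and HAT3 and by HAT1 (0.04 ± 0.21). A rise in part of the group stayed open, since 2 of 5 is neither most of the group nor none.

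For the comparison between organs in high R/FR, 1 of 100 splits of the 20 libraries, the real split, gave as many as 15897 genes. The highest of the others gave 10285, with 8 hypocotyl libraries on one side. The other splits mixed the organs without a term for organ, so the organ difference entered their spread. Their counts therefore cannot measure chance.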
